A study of Atractylodes macrocephala with 12 samples.

How the data were processed

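RNA was measured in rhizomes of Atractylodes macrocephala seedlings, in 12 libraries that the labels place in 4 groups of 3. The groups were healthy seedlings, seedlings infected with the root rot agent labelled FS and given sterile water (FS-water), infected seedlings given the endophytic bacterium AM201, and infected seedlings given the positive-control pesticide labelled TM. The labels do not spell out FS or TM. Deposited values of the healthy group are headed Water and those of the FS-water group FS, and the groups here follow the sample titles. Per the labels' protocols, first-strand cDNA was primed with oligo(dT), copied to full length by the SMARTer method, amplified by PCR, fragmented enzymatically and ligated to indexed adapters. The kit as described does not mark the strand, and no molecular identifiers are described.

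Per the submitters' processing notes, the authors used cutadapt, FastQC and Salmon, whose versions are not given in the sources used here. The deposited table held, per the file headers, estimated counts and TPM for each library beside the length and annotation of 105105 assembled genes. Counts need not be whole, and between 90.3% and 94.2% of the values of a library, genes at 0 included, were exactly whole with no tolerance. The gene identifiers are those of a Trinity assembly; the assembly's settings are not given in the sources used here, and no reference genome was used here, so no coordinates are given. One gene of the plant can be split over several assembled genes, and reads can be shared between similar assembled genes, so a value for one member of a family is uncertain. Protein matches were listed for 48888 genes, Swiss-Prot matches for 33585, GO terms for 42814 and KEGG orthology for 16557. Genes are named here by the description of their protein match in the deposited table.

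Estimated counts were rounded to whole numbers and summed to the depth of each library, from 14934344 to 22697914. Genes with low counts were removed with filterByExpr by group, which left 63580. Libraries were scaled by TMM, and each comparison was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 in 1 model over all 12 libraries, without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.775. CPM values are scaled by TMM. The main comparisons were FS-water with healthy, AM201 with FS-water, TM with FS-water and AM201 with TM; AM201 and TM were also compared with healthy. The labels number the replicates and do not say that they came from separate plants, so p-values measure the spread between these samples, which may be technical.

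The tests, the comparisons, 33 gene lists and the rule for named genes were fixed before the data were examined. The lists were matched to the annotation text and cover pathogenesis-related proteins, cell wall and secondary metabolism, hormones, transcription factors, immune receptors, antioxidant enzymes, cell division, transport, markers of other tissues, and names of fungi and bacteria. Lists can hold genes of other organisms. A best protein match in Asteraceae was listed for 516 of 524 NLR receptors and 55 of 73 terpenoid backbone genes. It was listed for 25 of 37 chitinases, 169 of 268 heat shock proteins and 46 of 84 antioxidant genes. The lowest of these shares were 75 of 159 bacterial names, 265 of 879 ribosomal proteins and 234 of 2310 fungal names. Each list was tested in the 4 main comparisons with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated correlation, and with fry, each adjusted over 132 tests. Camera compares a list with all other genes, while fry asks whether its genes move in 1 direction on balance. Of the 132 tests, 48 passed with camera at the preset correlation, 0 with the estimated correlation and 10 with fry. In TM against FS-water the estimated correlation was 0.06 for cell cycle, 0.149 for xylem and 0.466 for polyacetylene desaturase genes. It was -0.001 for MYB and NAC factors. Where it lay above the preset, the p-values at the preset are likely too small. GO and KEGG terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test among called genes, against the 31532 tested genes with a GO term or the 12488 with a KEGG pathway. Named genes were the 5 highest and 5 lowest fold changes among called, informatively annotated genes with at least 5 CPM over both groups and no overlap between groups. Up to 2 called members per list with the smallest adjusted p were added, or up to 4 in the lists described, and where no gene was called, the 5 with the smallest p were given as values. The text describes part of the genes that the rule gave. Genes outside that rule are marked as chosen after their values were seen.

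The edgeR steps were tested on simulated counts with 200 changed genes. A log2 change of 1 was recovered for 0% of the changed genes in every main comparison. A log2 change of 3 was recovered for 37.9% in FS-water against healthy (60118 genes), 45.5% in AM201 against FS-water (60103 genes), 36.4% in TM against FS-water (60262 genes) and 50.0% in AM201 against TM (60147 genes). Shares of counts carry 95% Wilson intervals, which cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The alternatives were RLE and upper-quartile factors, no filter and a stricter filter on low counts, only the groups compared, the replicate number as a block, DESeq2 1.42.0, limma on log2(TPM + 1), a fold threshold, genes naming a fungus or bacterium left out, and each library left out. Chosen after seeing the data were a restriction to genes whose best protein match is an Asteraceae species, limma voom with sample weights, leaving out 2 genes, a virus-like one and one with no match, that were abundant in healthy 2, and a term for the libraries with 4 or fewer counts of these 2 genes (the virus-trace term). Those libraries were FS-water 1 to 3 and TM 1 and 2, and the other 7 held 231 or more. All FS-water libraries were thus in the set, and all healthy and AM201 libraries outside it. The term could be estimated only from TM 3 against TM 1 and 2. It therefore cannot separate the set from infection or from AM201 in the comparisons of FS-water with healthy and with AM201. Other calculations used python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.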

Results

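Transcripts of Atractylodes macrocephala rhizomes were counted in 12 RNA-seq libraries, 3 each from healthy seedlings, FS-infected seedlings given sterile water, infected seedlings given AM201 and infected seedlings given TM. A. macrocephala is a medicinal plant of the daisy family (Asteraceae), AM201 is an endophytic bacterium that the series title assigns to Rhodococcus, and TM served as the positive-control pesticide against root rot. Total counts were 20227806, 19371639 and 18033258 in the healthy libraries, 20340988, 19359749 and 19434234 in FS-water, 20249114, 14934344 and 21218378 in AM201, and 18662976, 19369441 and 22697914 in TM. Of 105105 assembled genes, 63580 passed the count filter and were tested.

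Over all pairs, libraries of one group lay closer together on average than libraries of different groups. The mean distance (1 minus Spearman correlation over tested genes) was 0.0479 larger between than within groups (exact permutation p = 0.00247, 15400 partitions of the 12 libraries). TM libraries were the most alike, with a mean correlation of 0.894, against 0.820 within AM201, 0.785 within healthy and 0.768 within FS-water. This did not hold for each group: FS-water libraries correlated more with AM201 libraries (0.778) than with each other, and the mean for AM201 with TM (0.810) exceeded that within healthy. The lowest mean between groups was that of healthy with FS-water (0.737). Healthy library 2 stood apart: its 20 most abundant genes held 19.9% of its counts, against 4.77% to 10.4% in the other 11, and its TMM factor was 0.732. It correlated more with FS-water 1 (0.803) than with healthy 1 (0.729) or healthy 3 (0.769), and less with FS-water 2 (0.715).

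Genes whose best protein match was Quercus suber formed a fungal-type fraction, since 78.8% of their Swiss-Prot matches came from fungi, against 1.43% for genes with an Asteraceae match. This fraction held 1.87%, 1.69% and 1.04% of counts in the healthy libraries. It held 1.32%, 1.84% and 0.0866% in FS-water, 0.132%, 0.185% and 2.02% in AM201, and 0.134%, 0.152% and 0.0673% in TM. Counting error was small beside these differences (95% Wilson interval 1.86% to 1.87% in healthy 1 and 0.0853% to 0.088% in FS-water 3). The fraction did not part infected from healthy libraries, and within each of the 4 groups the 95% intervals of the libraries did not overlap, intervals that cover counting error only.

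**Figure D1:**
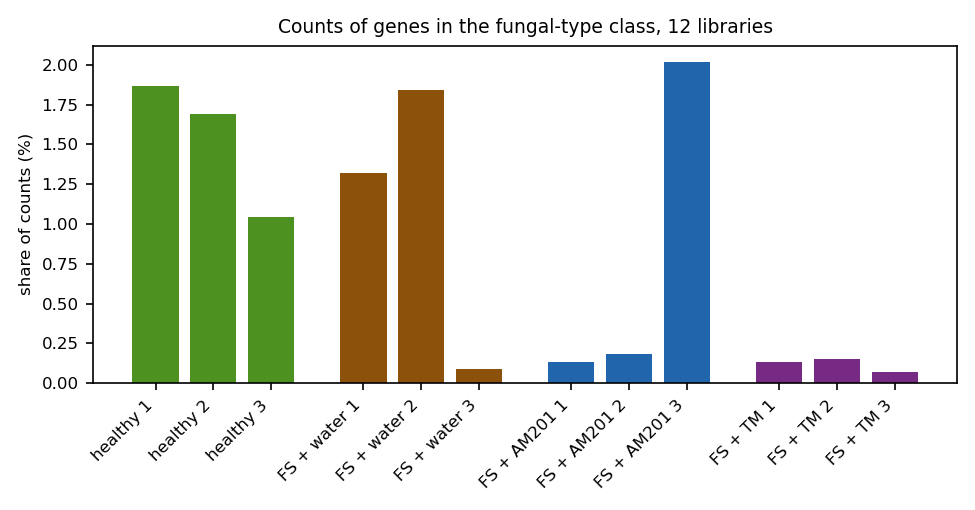
Bars give the share of all counts (%, axis from 0) that fell on the 7154 fungal-type genes, 1 bar per library, coloured by group. The 3 healthy libraries, FS-water 1 and 2 and AM201 3 lie at 1.04% or more, and the other 6 at 0.185% or less.

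The first comparison asked what infection with FS changed. The list of fructan metabolism, the making and breakdown of the storage carbohydrate of this plant family, had a median log2 change of 1.23 in FS-water against healthy rhizomes, with 7 of 10 genes higher, 3 lower and 0 called over all genes, and genes of xylem and secondary walls were lower, with a median of -1.22 over 44 genes of which 39 were lower. The fructan 1-exohydrolase gene TRINITY_DN47127_c0_g2, a fructan-degrading enzyme chosen after its values were seen, was at 240 ± 74.2 CPM against 55.8 ± 1.70 (mean ± SD, n = 3 each; log2 2.10, SE 0.33). It and 3 other members, TRINITY_DN57669_c2_g1, TRINITY_DN54665_c0_g1 and TRINITY_DN50679_c0_g1, were higher when adjusted over the list alone, with log2 changes of 1.75, 1.78 and 1.74, and were also chosen after their values were seen. Among the xylem genes 3 were lower when adjusted over the list alone, all chosen after their values were seen: an IRX15-like gene of xylan synthesis, TRINITY_DN38084_c0_g3 (log2 -2.91), and the fasciclin-like TRINITY_DN46606_c0_g1 (-2.43) and TRINITY_DN44838_c1_g12 (-2.60). Photosynthetic genes also had a higher median (0.41 over 65 genes), and 6 were higher adjusted over the list alone.

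These 3 lists passed camera at the preset correlation (adjusted p 0.00132 for fructan, 5.32e-11 for xylem and 0.00807 for photosynthetic genes) and fry (0.0323, 0.0324 and 0.0324). With an estimated correlation their adjusted p was 0.262, 0.269 and 0.269. The photosynthetic call was lost without healthy 3 (adjusted p 0.0823), with medians of 0.64 without healthy 2 and 0.19 without FS-water 1. The fructan call was lost with the virus-trace term (median 0.52, adjusted p 0.155), which marks the 5 libraries that nearly lack the 2 genes abundant in healthy 2. All FS-water libraries lie in that set and all healthy ones outside it, so the term cannot separate the set from infection here. Cell cycle and histone genes had a median of -0.41 over 333 genes, with camera adjusted p 2.43e-06, fry adjusted p 0.0629 and adjusted p = 0.274 with an estimated correlation. The call of the cell wall loosening genes (median -0.70 over 199 genes) and of the beta-1,3-glucanases (-0.68 over 63 genes) was lost without healthy library 2. Their medians were then -0.37 and -0.49, at adjusted p 0.0838 and 0.101. With an estimated correlation and all libraries their adjusted p was 0.536 and 0.441. Among lists of defence proteins, pathogenesis-related proteins had a median of -0.57 over 75 genes, chitinases -0.37 over 37 and class III peroxidases -0.59 over 76, while WRKY factors stood at 0.00 over 107 genes. The camera call of the pathogenesis-related proteins (adjusted p 0.0105) had adjusted p = 0.659 with an estimated correlation, and it was lost without healthy 2 (median -0.14, adjusted p 0.591), FS-water 2 (-0.44, 0.0867) or FS-water 3 (-0.59, 0.0778). It was also lost with the stricter filter (adjusted p 0.0925), only the groups compared (0.0769), voom weights (0.341), Asteraceae-match genes (0.232) and the virus-trace term (0.253). Its median was -0.97 without FS-water 1.

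Further lists passed camera at the preset correlation and not with an estimated one. These were NLR receptors (median 0.33 over 524 genes; adjusted p = 0.787 with an estimated correlation), phenylpropanoids (-0.26 over 184; adjusted p = 0.734 with an estimated correlation), polyacetylene desaturases (-0.33 over 46; adjusted p = 0.777 with an estimated correlation) and antioxidant enzymes (-0.39 over 84; adjusted p = 0.731 with an estimated correlation). Ribosomal proteins (-0.46 over 879; adjusted p = 0.536 with an estimated correlation), auxin genes (-0.16 over 179; adjusted p = 0.596 with an estimated correlation), fungal names (-0.21 over 2310; adjusted p = 0.846 with an estimated correlation) and bacterial names (-0.39 over 159; adjusted p = 0.659 with an estimated correlation) were the others. Each of these calls was lost without single libraries. Without healthy 2 the medians were -0.003 for NLR receptors (adjusted p 0.977), 0.022 for phenylpropanoids (0.701), -0.22 for polyacetylene desaturases (0.101), -0.12 for antioxidant enzymes (0.492), -0.05 for ribosomal proteins (0.101), -0.004 for fungal names (0.677) and -0.17 for bacterial names (0.385). Without FS-water 3 they were 0.10 for NLR receptors (0.327), 0.023 for polyacetylene desaturases (0.392), -0.17 for antioxidant enzymes (0.159), 0 for ribosomal proteins (0.718), 0.15 for fungal names (0.216) and -0.48 for bacterial names (0.412). The calls of phenylpropanoids (-0.23, adjusted p 0.134) and polyacetylene desaturases (-0.12, 0.114) were also lost without FS-water 2, and the ribosomal median was 0.08 without healthy 1. Without FS-water 1 medians were -0.50 for phenylpropanoids, -1.26 for polyacetylene desaturases, -0.73 for antioxidant enzymes, -0.43 for fungal names and -0.59 for bacterial names. Without FS-water 2 they were -1.12 for fungal and -0.76 for bacterial names. Without healthy 3 they were 0.59 for NLR receptors, -0.45 for fungal and -0.60 for bacterial names. Without healthy 1 they were 0.55 for NLR receptors and -0.18 for polyacetylene desaturases. Leaving out an AM201 or TM library gave ribosomal medians from -0.277 to -0.19, and leaving out AM201 3 gave -0.12 for fungal names. With voom weights the calls of NLR receptors (adjusted p 0.816), phenylpropanoids (0.385), polyacetylene desaturases (0.216), antioxidant enzymes (0.521), fungal names (0.776) and bacterial names (0.199) were lost. Calls were also lost over Asteraceae-match genes for phenylpropanoids (0.113), fungal names (0.508) and bacterial names (0.328). The virus-trace term ended those of phenylpropanoids (0.308) and polyacetylene desaturases (0.724). Others were lost with DESeq2 for NLR receptors (0.0571) and polyacetylene desaturases (0.125), with no filter for ribosomal proteins (0.141) and with the replicate block for antioxidant enzymes (0.0519). The auxin call was lost without healthy 1 (-0.18, adjusted p 0.0783), healthy 3 (-0.18, 0.0838), FS-water 1 (-0.29, 0.069) or FS-water 2 (-0.12, 0.173), with medians of -0.27, -0.30 and -0.26 without healthy 2, FS-water 3 or AM201 2, and also with upper-quartile factors, DESeq2, both other filters, only the groups compared, TPM, Asteraceae-match genes and the virus-trace term.

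No single gene passed the edgeR test over all genes in this comparison. The count was 0, with 8258 genes (13.0%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.155, while DESeq2 called 2831, of which 1372 were higher and 1459 lower. In 11273 genes (17.7%) the groups did not overlap, against 10% by chance for 3 against 3. The 5 informatively annotated genes with the smallest p, given as values, were a beta-D-xylosidase 2 gene at 440 ± 225 CPM in FS-water against 48.4 ± 15.3 in healthy (TRINITY_DN46974_c0_g2, log2 3.19, SE 0.45), a lectin/glucanase-domain gene (TRINITY_DN47228_c0_g3, 3.67, SE 0.53), an alpha/beta hydrolase gene (TRINITY_DN50290_c0_g5, -3.37, SE 0.43), a glucuronosyltransferase gene (TRINITY_DN51554_c0_g2, -2.34, SE 0.33) and an AFP3-like gene (TRINITY_DN40290_c0_g7, -2.92, SE 0.43). Each had an edgeR adjusted p of 0.155.

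The second comparison asked what AM201 changed in infected rhizomes. The NCED3-type dioxygenase gene TRINITY_DN38096_c2_g4, whose product makes the precursor of abscisic acid, was at 153 ± 119 CPM in AM201 against 6.86 ± 6.58 in FS-water (mean ± SD, n = 3 each; log2 4.48, SE 0.81), and was chosen after its values were seen. Its edgeR adjusted p over all genes was 0.341. It was at 36.6 ± 10.4 CPM in healthy and 46.0 ± 14.8 in TM rhizomes, also above FS-water. Of 68 genes in the abscisic acid list, 36 had higher and 32 lower values. When adjusted over the list alone 8 were higher and 1 lower, and 0 passed over all genes. The list was matched by annotation text, and not all of the 8 are described as abscisic acid genes. TRINITY_DN37802_c0_g1 is described as sorbose reductase-like, at 77.5 ± 132 CPM in AM201. TRINITY_DN43799_c1_g3 is described as uncharacterized, with a Swiss-Prot match to UDP-glycosyltransferase 73E1. Both were picked out after their values were seen. Genes of 2 protein phosphatases 2C, a family that restrains abscisic acid signalling, were among the 5 with the smallest p: TRINITY_DN45215_c0_g4 at 139 ± 59.1 against 16.7 ± 3.63 CPM (log2 3.06, SE 0.40) and TRINITY_DN53014_c0_g1 (3.45, SE 0.51). The others were a late embryogenesis abundant protein gene, TRINITY_DN50017_c0_g1 (5.31, SE 0.70), a bZIP-type regulatory factor gene, TRINITY_DN51089_c0_g4 (1.88, SE 0.28), and the IAA14-like auxin response gene TRINITY_DN49086_c0_g5 (2.46, SE 0.37). Their edgeR adjusted p ranged from 0.226 to 0.25, so none passed the threshold. In all 5 every FS-water library also lay below every healthy and every TM library, so low FS-water values are part of these contrasts. Every AM201 library lay above every healthy library for TRINITY_DN45215_c0_g4, TRINITY_DN50017_c0_g1 and TRINITY_DN51089_c0_g4. For TRINITY_DN53014_c0_g1 and TRINITY_DN49086_c0_g5 AM201 and healthy libraries overlapped.

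The abscisic acid list as a whole had a median log2 change of 0.07 and a camera adjusted p of 0.0414, with adjusted p = 0.269 with an estimated correlation and 0.0821 by fry. Auxin genes had a median of 0.30, with 116 of 179 higher (camera adjusted p 8.24e-05; adjusted p = 0.274 with an estimated correlation), and xylem genes a median of 0.55, with 36 of 44 higher (camera adjusted p 2.09e-05; adjusted p = 0.401 with an estimated correlation; median 0.29 without AM201 1). Polyacetylene desaturases were lower, with a median of -1.10 and 41 of 46 lower (camera adjusted p 3.02e-06; adjusted p = 0.659 with an estimated correlation). That median was -0.07 without FS-water 1 (adjusted p 0.831), -0.71 without AM201 2 (adjusted p 0.0603) and -1.75 without AM201 3. The abscisic acid call was lost without healthy 2 (median 0.03, adjusted p 0.0736), FS-water 1 (0.07, 0.0631), FS-water 2 (0.18, 0.141) or AM201 1 (-0.02, 0.0892). It was also lost with DESeq2 (adjusted p 0.0608), no filter (0.103), only the groups compared (0.0527), the virus-trace term (0.365) and Asteraceae-match genes (0.0831), over which its median was -0.007. Its median was 0.18 without FS-water 3, 0.02 without AM201 3, and from 0.042 to 0.043 without healthy 1, healthy 3, TM 1 or TM 2. The auxin call was lost with the virus-trace term (median 0.20, adjusted p 0.16), and the auxin median was 0.18 without FS-water 2. Names of fungi had a median of -1.27 over 2310 genes (adjusted p = 0.755 with an estimated correlation). Its call was lost over those with an Asteraceae match (-0.03, adjusted p 0.782), without FS-water 2 (-0.46, 0.134) and with the virus-trace term (0.15, 0.0824). Without AM201 3 that median was -3.51, without FS-water 3 -2.28, without AM201 2 -1.99 and without healthy 1 -1.92. Names of bacteria had a median of -0.17 over 159 genes (camera adjusted p 0.0437; adjusted p = 0.755 with an estimated correlation), a call lost with DESeq2 (adjusted p 0.136), TPM (0.0675), the stricter filter (0.111), only the groups compared (0.129), Asteraceae-match genes (0.805) and the virus-trace term (median 0.25, adjusted p 0.397). It was also lost without FS-water 1 (-0.20, adjusted p 0.0644), FS-water 2 (-0.05, 0.248), AM201 1 (-0.40, 0.241) or AM201 2 (-0.33, 0.0549). Its median was -1.92 without AM201 3 and from -0.39 to -0.266 without FS-water 3 or any single healthy or TM library. Of the 159 genes with bacterial names 75 had an Asteraceae best match, and cDNA was primed with oligo(dT). That list is therefore no measure of the amount of AM201 or of other bacteria. The antioxidant list of superoxide dismutase, catalase and ascorbate peroxidase had a median of -0.18 over 84 genes (camera adjusted p 0.00147; adjusted p = 0.596 with an estimated correlation). The antioxidant call was lost without FS-water 1 (-0.11, adjusted p 0.16) or AM201 1 (-0.23, 0.0634), with the stricter filter (0.0566), over Asteraceae-match genes (0.113) and with the virus-trace term (0.724). Its median was -0.53 without AM201 3.

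By edgeR 0 genes passed between AM201 and FS-water, with 5093 (8.01%) at an unadjusted p under 0.05, and DESeq2 called 1000, of which 324 were higher and 676 lower. A split that put FS-water 1, FS-water 2 and AM201 3 together called more by DESeq2, at 3587. The groups did not overlap in 6647 genes (10.5%), against 10% by chance. Salicylic acid genes had a median of 0.12 over 49 genes, jasmonate genes 0.06 over 102, ethylene genes -0.02 over 187, pathogenesis-related proteins 0.01 over 75 and immune receptors of the NLR type 0.06 over 524. None of these lists passed camera or fry. Mean and median differed in sign for jasmonate genes and pathogenesis-related proteins (means -0.01 and -0.07), and camera's direction was higher for ethylene genes, whose mean and median were negative.

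The third comparison asked what TM changed in infected rhizomes, and by edgeR it was the one comparison with FS-water in which single genes passed over all genes (DESeq2 called 2831 for FS-water against healthy and 1000 for AM201, and limma 7 for AM201). Of 63580 genes, 495 rose and 113 fell in TM, with a median size of the log2 change of 2.81, and in all 608 the libraries of both groups were apart. By the rule for named genes the 5 highest included a beta-caryophyllene synthase-like gene and the virus-like RNA2 polyprotein gene TRINITY_DN49096_c0_g1. The rest of the 5 were a leucine-rich repeat kinase gene (TRINITY_DN45275_c0_g4), a polygalacturonase gene (TRINITY_DN53759_c0_g5) and a DC2.15-like proline-rich protein gene (TRINITY_DN52037_c0_g12). Genes of sesquiterpene synthesis were among the most changed. The HMG-CoA reductase-like gene TRINITY_DN46481_c0_g3, of the mevalonate pathway that feeds sesquiterpenes, rose from 0.565 ± 0.292 to 55.4 ± 27.8 CPM (mean ± SD, n = 3 each; log2 6.59, SE 0.66, adjusted p 0.0089). A beta-caryophyllene synthase-like gene, TRINITY_DN54531_c0_g1, rose from 0.0492 ± 0.05 to 71.0 ± 36.9 CPM (log2 10.27, SE 1.33, adjusted p 0.0199), and a farnesyl diphosphate synthase gene, TRINITY_DN40632_c2_g3, from 4.73 ± 0.835 to 98.2 ± 39.9 CPM (4.37, SE 0.66, adjusted p 0.0243).

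**Figure D2:**
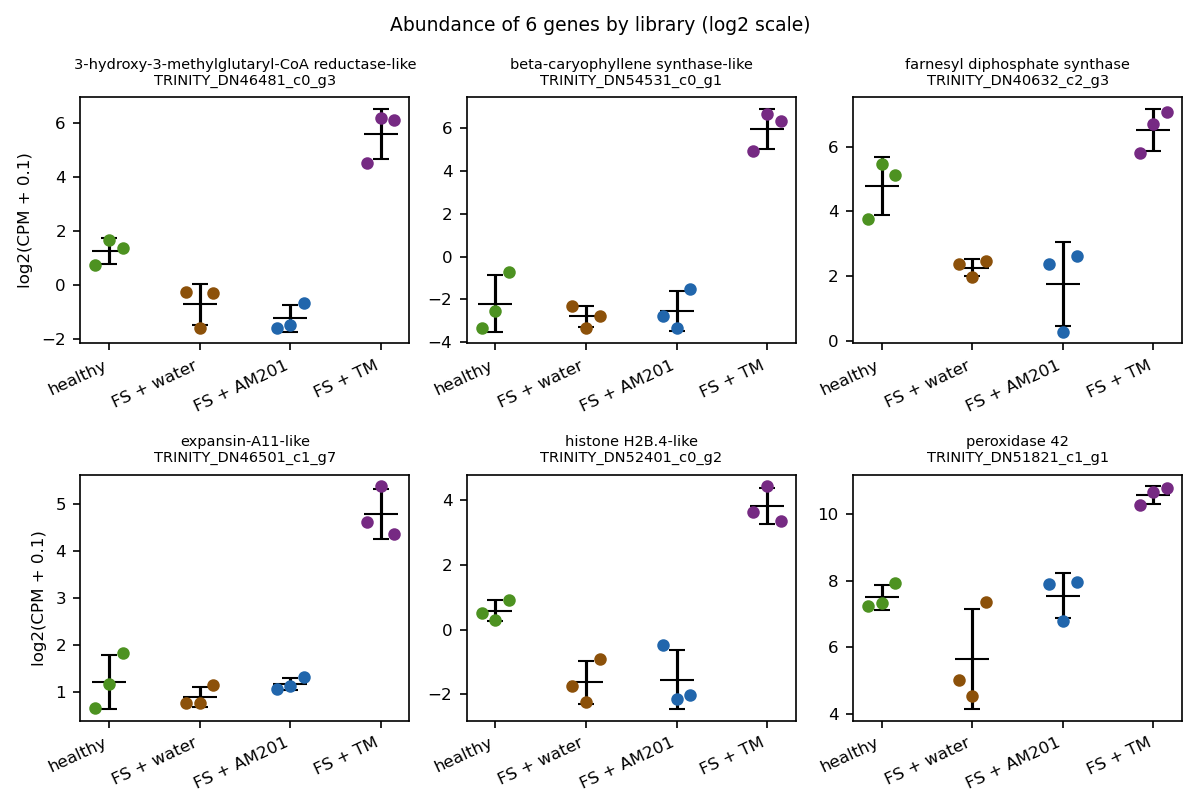
Abundance of 6 genes as log2(CPM + 0.1) in healthy, FS + water, FS + AM201 and FS + TM libraries; points are libraries, and horizontal lines with bars are the mean and SD of the log2 values (n = 3). The HMG-CoA reductase-like gene had a mean of 55.4 CPM in TM against 0.565 in FS-water, 0.345 in AM201 and 2.40 in healthy.

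Of 46 terpene synthases 5 rose and 0 fell, and 8 rose when adjusted over the list alone, with a median log2 change of 0.51, which was 0.11 without TM 2 and 0.08 without TM 3. Among them were an alpha-isocomene synthase, TRINITY_DN54531_c0_g3 (log2 6.56), and a beta-caryophyllene synthase, TRINITY_DN51897_c0_g2 (8.75). Of 73 genes of the terpenoid backbone 5 rose, and 13 rose and 2 fell adjusted over the list alone; their median was 0.25 and their mean -0.11, so these differ in sign. Members of both lists are similar to each other, and reads shared between them leave single values uncertain. The camera adjusted p was 0.000675 and 0.00207, with adjusted p = 0.274 and 0.571 with an estimated correlation. The terpenoid backbone call was lost without FS-water 3 (median 0.12, adjusted p 0.0876), and the median was 0.16 without FS-water 1, 0.14 without AM201 2 and 0.06 without TM 3.

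Of 333 cell cycle and histone genes 32 rose and 0 fell in TM, and 112 rose and 8 fell when adjusted over the list alone. The median log2 change was 0.73, with 237 values higher and 96 lower. A histone H2B gene, TRINITY_DN52401_c0_g2, rose from 0.248 ± 0.163 to 14.9 ± 6.09 CPM (log2 5.85, SE 0.78, adjusted p 0.0203), a histone H4-like gene, TRINITY_DN45085_c0_g7, rose by 5.25, and a kinesin of the microtubule motor family, TRINITY_DN41700_c1_g3, by 2.64 (SE 0.34). The list also holds a kinesin light chain-related gene that is not a motor, TRINITY_DN47760_c0_g7 (log2 8.18). The list passed camera at the preset correlation (adjusted p 1.24e-17) and fry (0.00903). It did not pass camera at its estimated correlation of 0.06 (adjusted p = 0.18). Nucleosome assembly was enriched among the genes that rose, with 17 of 92 tested genes against 1.32 by chance (Fisher's exact test, adjusted p 3.49e-11), and so were the tubulin complex with 14 of 59 and microtubule-based process with 15 of 69.

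Of 44 xylem and secondary wall genes 10 rose and 0 fell, and 27 rose adjusted over the list alone (median 1.76, with 38 values higher and 6 lower; camera adjusted p 9.31e-23; fry 0.00724; adjusted p = 0.18 with an estimated correlation). A fasciclin-like gene, TRINITY_DN46688_c2_g4, rose from 1.53 ± 1.03 to 107 ± 69.1 CPM (log2 6.11, SE 1.01), and the IRX15-like gene TRINITY_DN38084_c0_g3 by 4.34 (SE 0.75). Of 199 genes of wall loosening and pectin 10 rose and 0 fell, and 54 rose and 3 fell adjusted over the list alone (median 0.80, with 130 values higher and 69 lower; adjusted p = 0.274 with an estimated correlation). An expansin-A11-like gene, of a family that loosens walls, rose from 1.77 ± 0.29 to 28.7 ± 11.3 CPM (TRINITY_DN46501_c1_g7, log2 4.01, SE 0.43, adjusted p 0.0116). In the endodermis and root cap list 2 of 10 genes rose, the CASP-like TRINITY_DN50102_c0_g5 (3.47) and TRINITY_DN54144_c1_g3 (2.32). Adjusted over the list alone 4 rose (adjusted p = 0.274 with an estimated correlation). The list was matched by annotation text, and a CASP-like description does not by itself place a gene in the endodermis. Phloem markers had a median of 0.07 over 68 genes with 0 called. Cell wall organization (21 of 192 genes, adjusted p 2.81e-10), cellulose biosynthesis (10 of 63, 3.84e-06) and KEGG phenylpropanoid biosynthesis (13 of 171, 0.000836) were enriched among genes that rose; 51 terms passed for these and 0 for genes that fell.

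**Figure D3:**
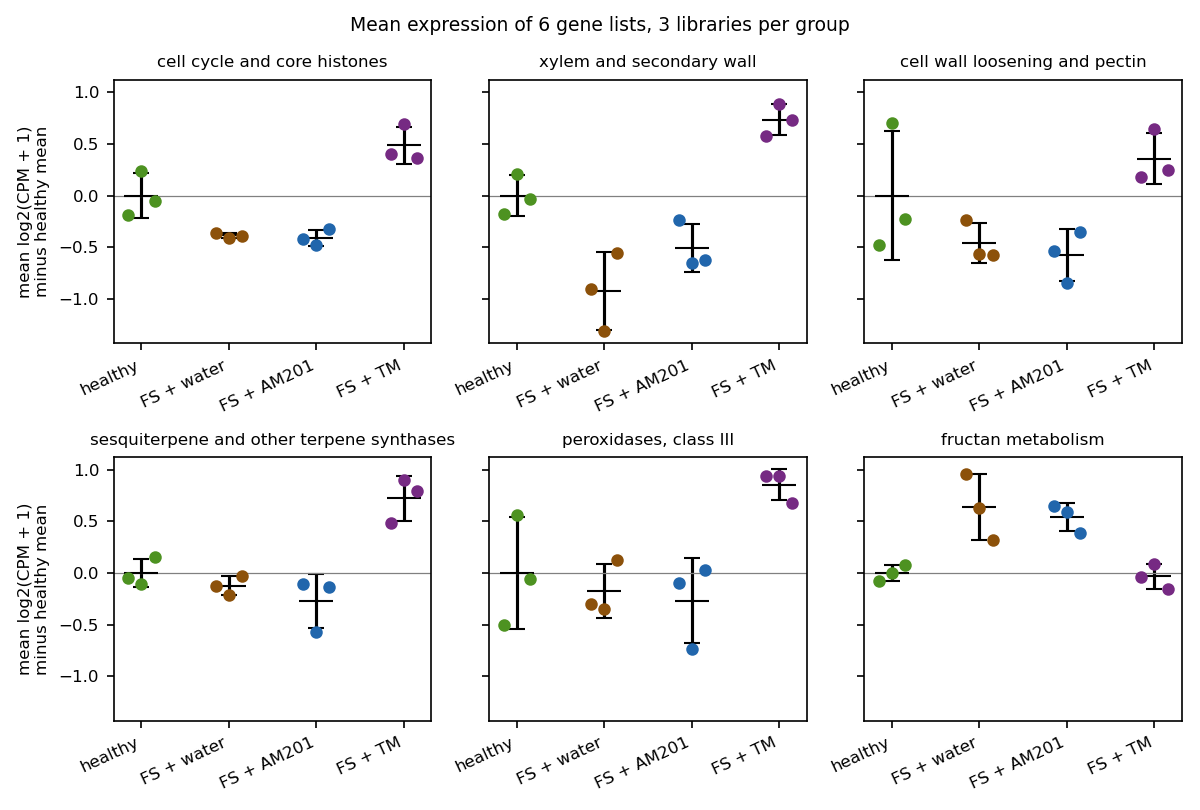
Mean log2(CPM + 1) over the genes of 6 lists minus the mean of the healthy libraries, by group; points are libraries, and horizontal lines with bars are the mean and SD (n = 3). Xylem scores were 0.73 ± 0.15 in TM and -0.92 ± 0.38 in FS-water (mean ± SD, n = 3 each), and cell cycle scores 0.49 ± 0.18 and -0.38 ± 0.02.

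Defence-related enzymes rose in TM in part. Of 76 class III peroxidases 5 rose and 0 fell, and 17 rose adjusted over the list alone (median 0.75; camera adjusted p 8.89e-08; adjusted p = 0.274 with an estimated correlation); peroxidase 42, TRINITY_DN51821_c1_g1, rose from 72.9 ± 78.5 to 1541 ± 278 CPM (log2 4.40, SE 0.73, adjusted p 0.0324). Of 184 phenylpropanoid and lignin genes 9 rose and 0 fell, and 31 rose and 3 fell adjusted over the list alone (median 0.44, or 0.79 without FS-water 1 and 0.20 without TM 3; adjusted p = 0.303 with an estimated correlation), with dirigent protein 21-like TRINITY_DN38618_c0_g4 at 4.58. Of 63 beta-1,3-glucanases 3 rose, and 16 rose and 1 fell adjusted over the list alone (median 0.43, or 0.78, 0.86 and 0.76 without healthy 3, FS-water 1 or FS-water 3; adjusted p = 0.303 with an estimated correlation). Of 75 pathogenesis-related proteins 2 rose, a kirola-like gene, TRINITY_DN46218_c1_g4 (6.53, SE 1.23), and a defensin-like gene, TRINITY_DN36864_c0_g1 (4.95, SE 0.88, adjusted p 0.0357). Adjusted over the list alone 12 rose and 1 fell (median 0.13, camera adjusted p 0.0899). Chitinases had 2 genes that rose and a median of -0.43 over 37, both chitinase-like wall proteins: TRINITY_DN46466_c1_g2 (2.69) and TRINITY_DN40715_c0_g9 (2.63). In that list 3 rose and 1 fell adjusted over the list alone. Flavonoid and WRKY lists had 0 called genes, with 0 adjusted over the list alone and medians of -0.03 over 79 and -0.22 over 107 genes.

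Some regulators fell and others rose in TM. A NAC104-like gene, TRINITY_DN39144_c0_g4, fell from 28.5 ± 11.5 to 3.74 ± 1.27 CPM (log2 -2.93, SE 0.39, adjusted p 0.0203), MYB62 (TRINITY_DN42928_c1_g1) fell by 2.26 on the log2 scale, and an auxin response factor 5-like gene (TRINITY_DN43199_c0_g1) by 2.43. The IAA14-like gene TRINITY_DN49086_c0_g5 rose from 12.1 ± 4.62 to 117 ± 35.6 CPM (3.28, SE 0.38, adjusted p 0.0168). Among 179 auxin genes 5 rose and 2 fell, with 26 and 12 adjusted over the list alone (median 0.21; adjusted p = 0.536 with an estimated correlation). The auxin call was lost without FS-water 2 (median 0.15, adjusted p 0.0883), over Asteraceae-match genes (0.09, 0.769), with the stricter filter (0.10, 0.183) and with only the groups compared (0.15, 0.172). Its median was 0.40 without FS-water 3 and 0.13 without TM 3. Among 102 jasmonate genes (median 0.23; adjusted p = 0.441 with an estimated correlation) 2 rose: bHLH18-like TRINITY_DN51032_c0_g3 (2.76) and a 12-oxophytodienoate reductase, TRINITY_DN38696_c0_g3 (3.10). The jasmonate call was lost without TM 3 (median 0.09, adjusted p 0.165), over Asteraceae-match genes (0.06, 0.684), with the stricter filter (0.17, 0.0729), with only the groups compared (0.17, 0.0924), with voom weights (0.18, 0.143) and with the virus-trace term (0.04, 0.276). Its median was 0.46 without FS-water 1. The chloroplast protease gene FTSH2 (TRINITY_DN54496_c0_g4) fell by 3.72. Of 10 fructan genes 0 passed over all genes and 3 were lower adjusted over the list alone (median -1.06; fry adjusted p 0.0324; adjusted p = 0.269 with an estimated correlation), and without FS-water 1 the camera adjusted p was 0.0647. Names of fungi had a median of -3.64 over 2310 genes with 2116 lower (adjusted p = 0.636 with an estimated correlation), and of -0.06 over those with an Asteraceae match (adjusted p 0.666). The mean score of these names in FS-water 3 (-1.35 relative to healthy) lay within the TM range of -1.351 to -1.13, while FS-water 1 and 2 stood at -0.01 and 0.34. The 2 of them that rose were a cell division control protein 45 homolog (TRINITY_DN56518_c1_g4) and an amino acid transporter (TRINITY_DN41975_c0_g2).

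Other fixed lists held few called genes in this comparison and passed neither camera nor fry. Medians were 0.05 for 187 ethylene genes (2 rose, 1 fell; 18 rose and 6 fell adjusted over the list alone), 0.06 for 49 salicylic acid genes (1 rose), 0.08 for 68 abscisic acid genes (1 rose) and -0.10 for 259 MYB and NAC factors (1 rose, 2 fell; 8 and 17 adjusted over the list alone). They were -0.01 for 524 NLR receptors (1 rose), -0.01 for 344 genes of pattern-triggered immunity (1 fell), -0.67 for 84 antioxidant genes (1 rose), -0.04 for 79 glutathione S-transferases (1 rose) and 0.01 for 268 heat shock proteins (4 rose). An Asteraceae best match was listed for 46 of the antioxidant genes, 52 of the glutathione S-transferases and 169 of the heat shock proteins. Values of these lists may thus include genes of other organisms. Adjusted over the list alone, 4 antioxidant genes rose and 2 fell, 8 glutathione S-transferases rose and 3 fell, and 14 heat shock proteins rose and 4 fell. Polyacetylene desaturases had a median of -0.50 over 46 genes with 0 called, ribosomal proteins -0.35 over 879 (1 rose), ABC and detoxification transporters 0.14 over 285 (3 rose), sugar and nitrate transporters -0.10 over 104 (2 rose), photosynthetic genes -0.14 over 65 (1 fell) and bacterial names -0.97 over 159 (1 fell). By the adjustment over the list alone, 8 ABC and detoxification transporters rose and 0 fell. The counts were 4 and 5 for sugar and nitrate transporters, 0 and 3 for photosynthetic genes, and 6 and 3 for bacterial names. The mean and median differed in sign for abscisic acid genes (mean -0.14), heat shock proteins (mean -0.49), NLR receptors (mean 0.05) and phloem markers (mean -0.03). Camera's direction was higher for ribosomal proteins, polyacetylene desaturases, NLR receptors, pattern-triggered immunity, glutathione S-transferases and flavonoid genes, whose medians were negative, and lower for phloem markers, whose median was positive. The nitrate transporter family gene TRINITY_DN57152_c0_g1 rose from 24.3 ± 6.28 to 212 ± 58.6 CPM (mean ± SD, n = 3 each; log2 3.12, SE 0.46, adjusted p 0.0243).

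The 608 calls changed with single libraries. Counts fell to 28, 0 and 28 without TM 1, 2 or 3, to 26 and 16 without FS-water 1 or 2, to 101 without healthy 3 and to 148, 307 and 166 without AM201 1, 2 or 3, and rose to 1123 without FS-water 3. DESeq2 called 6091 genes, 52.7% of them higher in TM against 81.4% by edgeR. The median log2 change of all genes was -0.14 with TMM and -0.25 with upper-quartile factors, and list changes are to be read against this shift. By non-overlap 14978 genes (23.6%) were apart, against 10% by chance, and 11269 had an unadjusted p under 0.05.

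The fourth comparison set AM201 against TM, which also tests whether their effects in infected rhizomes differed. In AM201 101 genes were higher and 261 lower than in TM, with a median size of the log2 change of 2.70. The HMG-CoA reductase-like gene TRINITY_DN46481_c0_g3 was at 0.345 ± 0.168 CPM in AM201 and 55.4 ± 27.8 in TM (mean ± SD, n = 3 each; log2 -7.29, SE 0.69, adjusted p 0.0103), and the farnesyl diphosphate synthase gene TRINITY_DN40632_c2_g3 at 4.07 ± 2.62 and 98.2 ± 39.9 (-4.58, SE 0.67, adjusted p 0.034). A laccase-5-like gene, of a family that couples lignin units, was at 0.576 ± 0.402 and 82.4 ± 56.3 (TRINITY_DN54695_c0_g2, -7.12, SE 1.08, adjusted p 0.034). Higher in AM201 were a U-box protein gene, TRINITY_DN40601_c1_g3 (3.48, SE 0.50), a BON1-associated protein gene, TRINITY_DN57171_c1_g4 (3.34, SE 0.37), and the MYB62 gene TRINITY_DN42928_c1_g1 (2.02, SE 0.31). MYB and NAC factors passed fry towards higher values in AM201 (adjusted p 0.0478), with 155 of 259 higher, 104 lower and a median of 0.15. Their mean was -0.01, and 3 were called higher and 1 lower. They did not pass camera at the preset (adjusted p 0.262) or an estimated correlation (0.269).

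Cell cycle and histone genes were lower in AM201 for 23 of 333, with 102 lower and 7 higher adjusted over the list alone (median -0.85; fry adjusted p 0.0107; adjusted p = 0.18 with an estimated correlation). The histone H2B gene TRINITY_DN52401_c0_g2 fell by 5.59 on the log2 scale relative to TM, and a mitotic cyclin gene, TRINITY_DN52164_c0_g1, by 3.37. Xylem genes were lower for 2 of 44, with 21 adjusted over the list alone (median -1.42; fry 0.0317; adjusted p = 0.269 with an estimated correlation), namely TRINITY_DN49726_c0_g4 (-1.80) and TRINITY_DN53513_c0_g8 (-3.96). Endodermis and root cap markers had a median of -1.93 with 9 of 10 lower, 0 called over all genes, and 6 lower and 1 higher adjusted over the list alone (camera adjusted p 0.000504; adjusted p = 0.274 with an estimated correlation). Terpene synthases were lower for 2 of 46, with 9 adjusted over the list alone (median -0.82; fry 0.0317; adjusted p = 0.262 with an estimated correlation), namely TRINITY_DN54531_c0_g1 (-9.34) and TRINITY_DN51897_c0_g2 (-8.86). The terpenoid backbone was lower for 5 of 73 (median -0.47; adjusted p = 0.274 with an estimated correlation), wall loosening for 8 of 199 (median -1.16, or -0.68 without TM 2; adjusted p = 0.274 with an estimated correlation) and phenylpropanoids for 5 of 184 (median -0.84, or -0.555 without TM 3; adjusted p = 0.274 with an estimated correlation). Adjusted over the list alone these counts were 16, 37 and 22. Class III peroxidases were lower for 1 of 76, with 14 lower and 2 higher adjusted over the list alone (median -1.23; adjusted p = 0.269 with an estimated correlation). Beta-1,3-glucanases had a median of -1.002 over 63 genes with 10 lower adjusted over the list alone and 0 called over all genes (adjusted p = 0.305 with an estimated correlation). Polyacetylene desaturases had a median of -0.80 over 46 genes (camera adjusted p 0.000341; adjusted p = 0.734 with an estimated correlation), a call lost without AM201 2 (-0.43, adjusted p 0.062), with medians of -1.42 without AM201 3 and -0.47 without TM 3. Names of fungi had a median of 1.22 over 2310 genes (camera adjusted p 0.000721; adjusted p = 0.846 with an estimated correlation). That call was lost without AM201 3 (median 0, adjusted p 0.513), without TM 3 (0.66, 0.11), over Asteraceae-match genes (0.04, 0.805) and with voom weights (0.48, 0.159). The median was 0.73, 1.87 and 0.77 without AM201 2, TM 2 or healthy 1. Fructan genes had a median of 1.02 with 0 called over all genes and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.274 with an estimated correlation), and their camera call was lost without healthy 2 (median 1.05, adjusted p 0.0736), FS-water 1 (1.01, 0.0505), FS-water 2 (1.01, 0.053), AM201 1 (0.81, 0.0892), AM201 2 (0.99, 0.0555) or TM 3 (0.97, 0.0539), and with DESeq2 (adjusted p 0.114), the stricter filter (0.0617) and only the groups compared (0.0933).

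Nucleosome assembly was enriched among the genes lower in AM201 (14 of 92, adjusted p 2.91e-11), as were the citrate cycle (9 of 93, 5.05e-05) and glycolysis (10 of 188, 0.0013). Terms of photosynthesis stood on both sides: photosynthesis among the genes lower in AM201 (6 of 78, adjusted p 0.00594) and the chloroplast thylakoid membrane among those higher (7 of 292, adjusted p 0.00705). A virus-like RNA2 polyprotein gene, TRINITY_DN49096_c0_g1, was at 0 in the 3 AM201 libraries and 76.7 ± 82.4 CPM in TM, at least 1440-fold higher in TM against a floor of 3 counts over the group. The 362 calls were 0 without AM201 1, 2 or 3, 4, 0 and 4 without TM 1, 2 or 3, 8 without healthy 3, 154 without FS-water 1, 892 without healthy 2 and 1005 without FS-water 2. DESeq2 called 6143 genes; 18435 (29.0%) did not overlap, against 10% by chance, and 11118 had an unadjusted p under 0.05.

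Against healthy rhizomes, edgeR called 0 genes for AM201 (9546 at an unadjusted p under 0.05; 3292 by DESeq2) and 0 for TM (9068 at an unadjusted p under 0.05; 3578 by DESeq2), with smallest adjusted p of 0.141 and 0.0675. Whether genes moved by infection moved back under treatment was asked by overlap of calls. By edgeR these overlaps were fixed at 0, since 0 genes were called in FS-water against healthy and in AM201 against FS-water (8258 and 5093 at an unadjusted p under 0.05), and they say nothing about such genes. By DESeq2, 157 genes called in FS-water against healthy were called in the opposite direction in AM201 against FS-water, against 22.02 for independent lists, and 1219 in TM against FS-water, against 136. Against FS-water, 406 genes were called the same way in both treatments and 6 in opposite ways, against 47.0 for independent lists.

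These comparisons share the 3 FS-water libraries, which cannot be split into parts of at least 2, so the excess over independent lists, in part or in whole, may come from the shared controls. In 10 simulations of unchanged groups DESeq2 called 154.4 genes on average for infection, 141.2 for AM201 and 147.2 for TM. The overlaps there were 26.3 on average for opposite calls with AM201 (at most 40), 24.8 with TM (at most 36) and 21.4 for calls shared by both treatments (at most 30). With no effect at all, overlaps thus lay above 0 through the shared controls. Pearson's correlation across genes, which are not independent replicates, of the infection change with the AM201 change was -0.36 against -0.50 in simulations of unchanged groups, and the covariance was -1.08 against -0.80 simulated. For the infection change with the TM change these were -0.35 against -0.50 and -1.06 against -0.80. For the AM201 change with the TM change the correlation was 0.55 against 0.50 simulated, and the covariance 1.964 against 0.80.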

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

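Of the tests in this part, the correlation of healthy 2 over plant genes and the search for reads of TM 1 in TM 2 over single genes with 1000 or more counts were set before their results were seen, and the others were chosen after the result was seen, except the call of 362 genes.

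In healthy library 2 an assembled gene that matches the RNA1 polyprotein of a cherry rasp leaf virus (2.29% of counts) and a gene with no protein match listed (9.27%) together held 11.6% of counts, against at most 111 and 477 counts in any other library. Over all genes this library lay near FS-water 1, and over 849 fungal-type genes its mean Spearman correlation was lower with healthy 1 and 3 than with FS-water 1 and 2 (difference -0.751), while over 29625 plant genes it was 0.873 and 0.828, so a wrong label on it alone stays open. A swap with FS-water 3 stays open too: for FS-water 3 the difference was -0.942 over fungal-type genes, but over plant genes it correlated 0.908 with healthy 1 and 3 and 0.885 with FS-water 1 and 2, and by DESeq2 the split with healthy 1, healthy 3 and FS-water 3 together called 4234 genes against 2832 for the groups, while over Asteraceae-match genes it called 1815 against 2023. Reads of other organisms are a candidate explanation for its place beside FS-water 1, since over plant genes its correlation with FS-water 1 was lower than its best with a healthy library, by a margin of only -0.006.

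Genes resembling a fabavirus and a potyvirus appeared in the TM libraries and hardly elsewhere, with 5183 counts in TM 1, 1414 in TM 2 and 437 in TM 3, against 6 in FS-water 3, 2 in healthy 3 and 0 in the other 7 libraries. The search set beforehand for reads of TM 1 in TM 2 found 6 of 3925 genes with 1000 or more counts under 0.5 times the viral ratio of 0.273, short of its bound of 10, and at 200 or more counts 86 of 15981, with 9 at 0. With counts summed over assembly clusters, which keeps together reads that similar genes share, 32 of 12432 clusters with 200 or more counts lay under it against 0.0126 by counting error (6 of 4785 at 1000 or more; 0 at 0), the most abundant with 25508 counts in TM 2 where carried reads alone would bring 72734, which argues against TM 1 reads carried over in proportion as the whole source. The proportion of both viruses did not differ beyond counting error between the TM libraries (chi-square p = 0.641, which compares these libraries and takes amplified reads as independent), and a source shared by the TM samples is a candidate explanation. Separate infections stay open, since the ratio of ratios of TM 2 to TM 1 (0.955) is possible under both.

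Cell cycle and xylem genes were higher in TM than in FS-water, and the direct comparison of AM201 with TM, which tests whether the effects of both treatments differ, called 362 genes. For cell cycle genes in TM against FS-water, reads of other organisms are argued against, since over Asteraceae-match genes the median was still 0.678. This value does not cover xylem genes, 38 of 44 with an Asteraceae match, or the 362 calls, 321 with one. The set of libraries that nearly lack the 2 genes abundant in healthy 2 is argued against for both lists in TM against FS-water. Within the set of FS-water 1 to 3 and TM 1 and 2 the lowest TM score lay above the highest FS-water score. The gap was 0.763 for cell cycle and 1.132 for xylem genes. For the 362 calls this set of libraries stays open. The AM201 libraries hold 231 or more counts of those 2 genes, and TM 1 and 2 hold 2 and 4. With the set as a term 3 of the 362 were still called. The median size over all 362 was 2.64 against 2.70, with a median SE of 0.58 against 0.45. In TM against FS-water 74 of 608 were still called (2.88 against 2.81, SE 0.53 against 0.49). These close folds say little, since the term rests on TM 3 against TM 1 and 2. The genes were called on a small spread that includes this difference. Over the whole lists in AM201 against TM the medians with the term were -0.59 against -0.85 for cell cycle and -1.17 against -1.42 for xylem genes. In TM against FS-water they were 0.80 against 0.73 and 1.75 against 1.76. If a lower share of the main cell type raised all other cell types alike, xylem and phloem markers would rise alike. The xylem change exceeded the phloem change by 1.657 (SE 0.225). This does not cover a shift in which tissues change unequally. Both lists were matched by annotation text, and a description such as fasciclin-like or PP2-like does not by itself place a gene in xylem or phloem. The gap therefore compares 2 lists and does not measure shares of tissue. A larger share of xylem, endodermis or dividing tissue in the TM rhizomes, and an effect of TM on these genes, both stay open and could not be separated here. The fabavirus-like and potyvirus-like genes were also found in the TM libraries and hardly elsewhere. Presence of these viruses therefore cannot be told apart from TM in these lists or calls.

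In AM201 library 3 the fungal-type genes held 2.02% of counts, above the highest healthy library at 1.87%, and their profile correlated 0.599 with healthy 1 and 3 and 0.255 with AM201 1 and 2 (plant genes 0.906 and 0.928).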

How the results depend on the processing

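Restriction to Asteraceae-match genes, voom with sample weights, leaving out the 2 genes abundant in healthy 2 and the virus-trace term, for the libraries that nearly lack these 2 genes, were chosen after seeing the data. The virus-trace term rests on TM 3 against TM 1 and 2, since every other group lay wholly inside or wholly outside the set. The cause of the changes below was not tested.

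The order of values is TM against FS-water, then AM201 against TM, where the main counts were 608 and 362. No filter on low counts gave 337 and 67, the stricter filter 960 and 892, only the groups compared 60 and 4225, limma on log2(TPM + 1) 1509 and 1094, Asteraceae-match genes 2066 and 1861, voom weights 1291 and 5680, the virus-trace term 74 and 7, and DESeq2 6091 and 6143. RLE and upper-quartile factors stayed within 1.5 times. The share of calls that were higher in TM than in FS-water was 81.4% by edgeR, 52.7% by DESeq2 and 66.8% over Asteraceae-match genes.

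Comparisons with a count of 0 by edgeR gave 2831 by DESeq2 for FS-water against healthy. AM201 against FS-water gave 1000 by DESeq2 and 7 by limma. AM201 against healthy gave 3292 by DESeq2, 93 by limma, 5 with only the groups compared, 5 over Asteraceae-match genes, 100 with voom weights and 1 with the virus-trace term. TM against healthy gave 3578 by DESeq2, 195 by limma, 6 with the stricter filter, 1539 with only the groups compared, 35 over Asteraceae-match genes and 2227 with voom weights. Opposite calls were 157 for AM201 and 1219 for TM by DESeq2, and shared calls of both treatments were 406 by DESeq2 and 4 by limma. Terms of 20 to 200 genes left 0 of 1 term for genes higher in AM201 than in TM.

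With the replicate number as a block the counts were 27 and 0. The numbers do not pair the libraries: of 18 pairs with one number 3 correlated above 0.1, from -0.259 to 0.294, and 4 of 12 libraries correlated best with their own number.

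Leaving out each library in turn gave 0 to 1123 calls for TM against FS-water, 0 to 1005 for AM201 against TM, 0 to 1 for FS-water against healthy, 0 to 5 for AM201 against FS-water, 0 to 1 for AM201 against healthy and 0 to 12 for TM against healthy. Opposite calls ranged from 0 to 0 for AM201 and 0 to 1 for TM, and shared calls from 0 to 5. The distance between groups ranged from 0.0341 to 0.0696, and gene list calls from 36 to 48.

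Of 3461 values of named genes under alternatives, 2096 kept their side of the threshold, 1352 lost the call, 13 gained one and 0 changed direction. Of 1194 list values, 1079 kept the call, 105 lost it and 10 changed direction, of the test or of the median. Over Asteraceae-match genes these were fungal names in FS-water against healthy (0.071) and abscisic acid genes in AM201 against FS-water (-0.007), and with the virus-trace term fungal names (0.151) and bacterial names (0.254) in AM201 against FS-water. The others came with 1 library left out. In FS-water against healthy the medians then ranged from -1.119 to 0.148 for fungal names, -0.499 to 0.022 for phenylpropanoids, -0.003 to 0.589 for NLR receptors, -1.26 to 0.023 for polyacetylene desaturases and -0.643 to 0.079 for ribosomal proteins, and in AM201 against FS-water from -0.023 to 0.184 for abscisic acid genes. The fructan call in FS-water against healthy was lost with the virus-trace term (adjusted p 0.155). At this depth and spread, simulated log2 changes of 1 were not recovered, so a count of 0 does not show that genes were unchanged.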

Other observations

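The counts over other splits of the samples were chosen after the result was seen, as were the genes named here, which passed only when adjusted over the list alone; the gene lists and their tests, and leaving out single libraries, were set beforehand.

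Sugar transporter genes were among those with higher values in FS-water than in healthy rhizomes. The ERD6-like gene TRINITY_DN53133_c0_g2, of a family that exports sugar from the vacuole, was at 1251 ± 814 CPM against 129 ± 69.3 (mean ± SD, n = 3 each; log2 3.28, SE 0.61), and the sugar transport protein 14 gene TRINITY_DN51616_c1_g1 at 514 ± 176 against 172 ± 45.7 (1.58, SE 0.39). In the list of 104 sugar and nitrate transporters, 4 were higher and 1 lower adjusted over the list alone, with a median of 0.16 over the whole list (camera adjusted p 0.287). Heat shock genes had a median of -0.20 over 268 genes, with 5 lower adjusted over the list alone (camera adjusted p 0.00139; adjusted p = 0.303 with an estimated correlation). The class I small heat shock gene TRINITY_DN45844_c0_g8 was at 22.8 ± 15.0 CPM in FS-water against 176 ± 34.2 in healthy (-2.95, SE 0.54). The list call was lost without FS-water 3 (adjusted p 0.164), with no filter (0.0513) and with the virus-trace term (0.365), and its median was -0.42 and -0.36 without FS-water 1 or 2.

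In AM201 against FS-water the peroxidase gene TRINITY_DN53388_c0_g2 was at 276 ± 50.5 CPM against 85.2 ± 12.01 (mean ± SD, n = 3 each; log2 1.69, SE 0.22), and the MYB41 gene TRINITY_DN51511_c0_g7 at 26.9 ± 3.02 against 3.03 ± 1.42 (3.15, SE 0.48). Each was the 1 member of its list to pass when adjusted over the list alone. The 76 class III peroxidases had a median of -0.09 (camera adjusted p 0.77). The 259 MYB and NAC factors had a median of 0.02 (camera adjusted p 0.758).

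The 6 libraries of a comparison form 10 splits, so the share of splits with as many calls cannot be under 0.05. TM against FS-water called 608 genes and the highest other split 0 (1 of 10 splits called as many), and AM201 against TM called 362 and the highest other 0 (1 of 10). FS-water against healthy, AM201 against FS-water and TM against healthy called 0 in every split (10 of 10), and AM201 against healthy called 0 with 1 in the highest other (10 of 10). By DESeq2, AM201 against FS-water called 1000 genes, and the split that put FS-water 1, FS-water 2 and AM201 3 together called 3587. FS-water against healthy called 2832 with the same tool refitted (2831 in the fit of the report; the cause of the difference was not tested), and the split with healthy 1, healthy 3 and FS-water 3 together called 4234. Both splits point to a structure of the samples apart from the groups. In the AM201 split, FS-water 1, FS-water 2 and AM201 3 held 1.32%, 1.84% and 2.02% fungal-type counts. The shares in FS-water 3, AM201 1 and AM201 2 were 0.0866%, 0.132% and 0.185%. The healthy split was not parted in this way, since healthy 1 and FS-water 3, put together, held 1.87% and 0.0866%. Whether fungal-type reads brought the calls was not tested. Over Asteraceae-match genes the real grouping of FS-water and healthy called 2023 and the highest other split 1815, and TM against FS-water called 6091 against 1295 by DESeq2, so the groups called the most in these.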
